A study of Homo sapiens with 21 samples.

How the data were processed

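RNA from 21 untreated human cancer cell lines was read on Illumina BeadChip expression arrays, 1 array per line. The labels give the tissue of origin as the only grouping: 11 hepatocellular carcinoma (HCC) lines, 5 lung cancer lines and 5 pancreatic cancer lines. The lines are independent of one another and each was read once, so no p-value below measures repeat arrays of one line. P-values of single genes, correlations and whole profiles rest on the spread between lines. Those of the camera test compare the genes of a list with other genes, and those for neighbouring genes compare with random sets of genes. A small p-value of these last kinds does not show that a difference repeats over lines. The dependence of each line on LSD1, which the series was set up around, is not given in the labels and was not analysed here.

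The authors processed the arrays in BeadStudio; its version is not given in the sources used here. The deposited raw tables hold intensity per gene, the average bead signal before normalization between arrays, per the file headers. The deposited detection p-value beside each intensity compares it with the negative controls of the array. How several probes of a gene were summarised, and whether a background was subtracted, are not given in the sources used here. In these tables a gene can be bright and still miss the detection threshold, and the reason was not tested. The authors also deposited processed intensity values on a linear scale, whose columns have nearly the same median within each of 2 tables but not between them; the method of that normalization is not stated. Each of the 21 processed columns correlated best with the raw column of its own line.

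The HCC lines and the other lines were read on different array designs. The HCC tables list 37879 genes, and 34601 are listed for the lung and pancreas lines. The symbols shared by all raw tables number 28501, with 9377 found only in the HCC tables and 6100 only in the lung and pancreas table. In the comparison of HCC lines with the others, array design and tissue cannot be told apart. The genome build behind the array annotation is not stated, so no coordinates are given; a reference annotation served to update older gene names and to order genes along chromosomes. Names matched through it were taken over, and other names stand as listed.

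Background was corrected with the normal-exponential model of limma 3.58.1 in R 4.3.3. The choice fixed before the data were examined was limma's own fit of the negative controls from detection p-values (neqc). That fit put the control mean at 858.8 to 2606 in the 2 tables of 10 lines and left the corrected values of any array there within at most 0.149 log2, so it was replaced after the data were seen. In its place the mean and SD were read from the median signal at each detection p-value, with means of 86.19 to 177.2 in those tables and a range of at least 11.1 log2 per array. The replaced fit stands among the alternatives, but with values so compressed it does not test the results. An offset of 16 was added, and arrays were quantile normalized and taken to log2. The 10 lung and pancreas lines were normalized on their own for their comparison, and all 21 lines on the shared symbols for the HCC comparison. Where several listed names led to 1 gene, the brightest was kept. Genes with a detection p-value under 0.05 in at least 3 lines were tested. Array precision is limited by their number, 1 per line.

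Groups were compared with limma (lmFit and eBayes) at a Benjamini-Hochberg adjusted p of 0.05 with no minimum fold. HCC was set against the mean of the lung and pancreas group means. In total 31 gene lists, fixed before the data were examined, were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry beside it. Counts of list members given as adjusted over the list alone use the p-values of that list's members only. Where a gene was not detected in any line of 1 side, its fold is a lower bound, taken against the mean, over those lines, of the higher of the lowest detected signal of the array and the gene's own value. After the data were seen, the same bound was given to named genes detected in a minority of the lines of the lower side, with only its undetected lines so replaced. Such bounds allow for the detection limit only and are not confidence limits. The spread between lines does not enter them, so a difference that did not pass is not established by its bound. Similarity within and between tissues was compared with an exact permutation test over all 252 splits of the 10 lines. Pearson and Spearman correlations of KDM1A with list means used permutation p-values from 100000 permutations, adjusted over 8 relations. Python 3.11.15 with pandas 2.3.3 and SciPy 1.17.1 computed these.

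Genes to name were chosen by a rule fixed before the data were examined: per comparison up to 10 genes in each direction with the largest change past the threshold, or the 5 with the smallest p where under 5 passed, up to 4 members of each list, and KDM1A. The text names 41 of the 140 genes this rule picked in the HCC comparison and 32 of 131 in the lung and pancreas comparison. This choice was made after the alternatives were seen, and picked HCC genes that lost their call in many of them, such as ESRP1, PFKFB4, KDM4C and OASL were left out. Results for some genes are not reported here. On simulated data with 200 shifted genes, the lung and pancreas fit recovered 0.3% of shifts of 1 on the log2 scale, 55.2% of shifts of 2 and 88% of shifts of 4. The HCC fit recovered 30.8%, 77.9% and 97.7%. At most 6.14% of the genes called in these runs were wrong. The runs drew each gene independently from a normal distribution, whereas real genes vary together, so these rates need not hold for the real lines.

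Alternatives fixed beforehand covered background correction, normalization, the filter on dim genes, probes of a gene, variance moderation, a minimum fold of 2, the deposited processed values, array weights, the lines in the fit, the raw table as a random block, the comparison group and leaving out each line in turn. Further alternatives, among them fits without the libraries labelled Hep3B, Malme-3M, Calu-3 and Capan-2, were added after the data were seen.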

Results

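Gene expression was measured once in each of 21 cancer cell lines grown without treatment. The HCC lines were HLF, JHH-4, JHH-6, Huh-1, SK-HEP-1, SNU-739, Hep3B, SNU-423, SNU-886, PLC/PRF/5 and SNU-475. The lung group held Calu-3, NCI-H596, NCI-H1299, Malme-3M and Calu-1, where Malme-3M is known as a melanoma line taken from a lung metastasis. The pancreatic group held MIA-PaCa-2, AsPC-1, BxPC-3, Capan-2 and Capan-1. Of the listed genes, 40.7% to 43.7% were detected in the lung and pancreas lines and 32.6% to 35.1% in the HCC lines other than Hep3B, where 24.9% were. The 95th percentile of raw signal stood 32.7 to 42.9 times over background in the lung and pancreas lines, 10.1 to 26.0 times in the other HCC lines and 4.78 times in Hep3B. On the first principal component of all 21 lines, which held 20.8% of the variance, Hep3B lay at -247.4 and the other lines between -39.96 and 53.46.

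The first comparison asked how lung and pancreatic cancer lines differ in expression, within 1 array design. BTBD6, an adaptor of a cullin ubiquitin ligase, was 44.8-fold higher in the lung lines, at 12.07 ± 0.10 (log2 intensity, SD, n = 5) against 6.59 ± 0.43 in the pancreatic lines (SD, n = 5), a log2 difference of 5.48 with a standard error of 0.23. It was the only gene of 16791 tested to pass (limma, adjusted p = 4.23e-06), and all lung lines stood above all pancreatic lines. The size depends on the processing: without background correction, and with the deposited processed values, the log2 difference of BTBD6 was 4.40. KDM1A, which encodes the histone demethylase LSD1 and is listed on the array as AOF2, averaged 11.92 ± 0.55 in lung and 11.86 ± 0.32 in pancreatic lines, a log2 difference of 0.06 with a standard error of 0.29 (limma, adjusted p = 0.9999). In the HCC lines, on the other array design, BTBD6 averaged 9.54 ± 2.28 (SD, n = 11) and was detected in 9 of 11.

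Genes with the next smallest p-values did not pass, and their values follow without a call. SNTB1, a syntrophin of the dystrophin complex, was at 10.38 ± 0.98 in lung and detected in 1 pancreatic line (log2 difference at least 4.41, limma adjusted p = 0.0848). The log2 difference was 1.82 for MAGED1, 3.03 for the Notch target HEY1 and 1.37 for IRF2BPL. On the pancreatic side CDX2, a homeobox regulator of intestinal identity, averaged 8.84 ± 1.02 in pancreas and was detected in 1 lung line (lower there by at least 3.22 on the log2 scale, limma adjusted p = 0.141). PDX1, a homeobox regulator of pancreas development, was not detected in any lung line and in 4 of 5 pancreatic lines, with a pancreatic mean at least 4.36-fold higher. The differences were -2.50 for PLCG2, -1.87 for the small RNA gene RNY4 and -1.41 for SFR1. An unadjusted p under 0.05 was reached by 611 genes, 3.64% of those tested. This lies below the share of 0.05 that chance alone would give. Groups did not overlap in 104 genes, 0.619%, where chance gives 0.794%.

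The call for BTBD6 held without each line in turn, and with the 3 libraries whose markers depart from their labels left out. The count of genes was 3 without Calu-3, 2 without NCI-H1299, AsPC-1 or Capan-2, 4 without BxPC-3 and 3 without Calu-3, Malme-3M and Capan-2. SNTB1 passed without NCI-H1299 (limma, adjusted p = 0.0363), without Capan-2 (adjusted p = 0.0205) and with detection p under 0.01 in at least 5 lines (adjusted p = 0.0445). CDX2 passed without BxPC-3 (adjusted p = 0.00597), as did LDHB (adjusted p = 0.00698). Fitted with all 21 lines, BTBD6 kept a difference of 5.47 but not its call (limma, adjusted p = 0.117), and CDX2 was the single gene to pass. KDM1A, not called in any fit, turned to a difference of -0.17 without Malme-3M and -0.06 without AsPC-1.

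**Figure D1:**
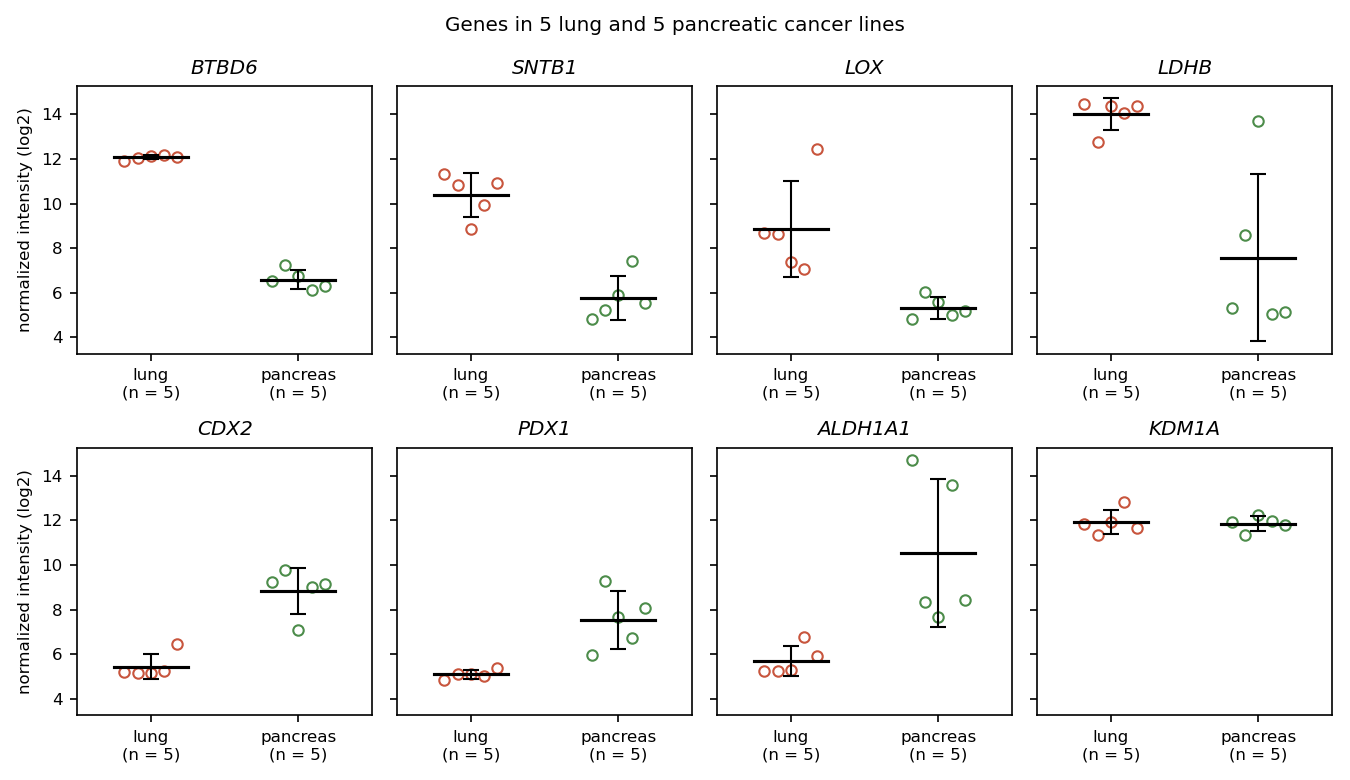
Normalized intensity (log2, vertical axis) of 8 genes in 5 lung and 5 pancreatic cancer lines; circles are lines, bars are means and error bars 1 SD. BTBD6 separates the groups with 12.07 against 6.59, whereas KDM1A averages 11.92 and 11.86.

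Of the 31 gene lists, 6 differed between lung and pancreas lines by camera, and none of their members passed among all genes. Proliferation genes lay higher in lung lines, with 28 of 30 positive and a median log2 difference of 0.69 (camera, adjusted p = 0.00039, and adjusted p = 0.853 with an estimated correlation). CENPF, a kinetochore protein, had a difference of 1.59 and TPX2, a spindle assembly factor, of 1.31. Glycolysis genes were positive in 20 of 21 (median 0.27, adjusted p = 0.00642, and adjusted p = 0.701 with an estimated correlation). The lactate dehydrogenase gene LDHB, the 1 member past the threshold adjusted over the list alone, averaged 14.0 ± 0.71 in lung and was detected in 2 pancreatic lines, a difference of at least 6.30, and PFKFB4 had 1.48. Cancer-testis antigens were positive in 10 of 13 (median 1.14, adjusted p = 0.0103, and adjusted p = 0.853 with an estimated correlation), among them CSAG2 with at least 2.09 and CSAG1 with 2.65.

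Pancreatic ductal genes lay lower in lung lines in 18 of 20 (median -0.78, camera, adjusted p = 0.0057, and adjusted p = 0.853 with an estimated correlation), with the mucin gene MUC13 lower by at least 1.96. CTSE, detected in 1 lung and 2 pancreatic lines, is given no difference. PDX1, given above as a bound, was the 1 ductal gene that passed adjusted over the list alone. Epithelial junction and identity genes were negative in 26 of 29 (median -0.98, adjusted p = 0.00642, and adjusted p = 0.853 with an estimated correlation), with LSR, a tricellular junction protein, at -1.57 and the claudin CLDN4 at -0.75. Leukocyte genes were negative in all 8 tested (median -0.79, adjusted p = 0.0103, and adjusted p = 0.616 with an estimated correlation), with CD14 lower by at least 1.64 and LYZ by at least 1.47. LSR, CLDN4, CD14 and LYZ did not pass, and 0 epithelial or leukocyte genes passed adjusted over the list alone. The log2 differences of CD14 and LYZ had standard errors of 0.95 and 0.98, of which their bounds take no account. In the pluripotency and stem cell list, the aldehyde dehydrogenase ALDH1A1 alone passed adjusted over the list alone. It was not detected in any lung line and at least 27.2-fold higher in pancreas, with 10.54 ± 3.34 there, and its limma adjusted p among all genes was 0.9999. In the mesenchymal list, without a call (camera, adjusted p = 0.0848), the collagen cross-linking enzyme LOX was not detected in any pancreatic line and was at least 9.77-fold higher in lung, without passing, and COL6A2 had at least 1.78. In other lists without a call, values were 2.14 for CCN2, 1.49 for the lipid droplet protein PLIN2, 0.90 for the histone demethylase KDM5C and 3.65 for BNIP3. The LSD1-CoREST complex list had a median of 0.09 over 19 members (camera, adjusted p = 0.877), with the LSD1 partners GFI1 at -1.53 and INSM1 at -0.38.

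With an estimated inter-gene correlation 0 lists passed. By fry 0 lists passed, with 1 at an unadjusted p under 0.05, against 11 by camera. Without AsPC-1, whose proliferation mean was 8.04 against 11.13 to 11.71 in the other pancreatic lines, 0 lists passed, and the proliferation median was 0.06 (adjusted p = 0.964) and the glycolysis median 0.11 (adjusted p = 0.148). Without NCI-H1299 3 lists passed and without Malme-3M 10. The ductal call was also lost without BxPC-3 (adjusted p = 0.0942) or Capan-1 (0.0953), and the leukocyte call without NCI-H596 (0.0517) or NCI-H1299 (0.0697). With no filter on detection, which admits the leukocyte members that missed it, the leukocyte median was -0.07 (adjusted p = 0.186). Without Calu-3, Malme-3M and Capan-2, a fit chosen after the data were seen, the glycolysis (median 0.15, adjusted p = 0.449) and cancer-testis (1.29, adjusted p = 0.136) calls were lost and the mesenchymal list gained one (0.42, adjusted p = 0.0197). The cancer-testis call was lost without NCI-H1299 (0.0925), MIA-PaCa-2 (0.12) or Capan-1 (0.0858), and the epithelial call without Calu-3 (0.0834), NCI-H1299 (0.102), Calu-1 (0.116), BxPC-3 (0.221) or Capan-1 (0.296). The mesenchymal list gained a call without NCI-H596 (median 0.58, adjusted p = 0.00716) or Malme-3M (0.34, adjusted p = 0.0317).

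Whole profiles were also compared, to see whether lines of 1 tissue resemble each other. The mean pairwise Pearson correlation was 0.852 within tissues and 0.856 between them, a difference of -0.00414 (exact permutation test, two-sided, p = 0.556 over 252 splits, smallest possible 0.00794). Of the 10 lines, 6 were nearest to a line of their own tissue, among them BxPC-3 and Capan-1 to each other with 0.911, and 4 to a line of the other. NCI-H596 was nearest to the pancreatic line Capan-1 with a correlation of 0.895, MIA-PaCa-2 was nearest to NCI-H1299 with 0.886, and Capan-2 and NCI-H1299 were nearest to each other with 0.907. The sign turned without MIA-PaCa-2 (0.000793) and without Capan-2 (0.00575).

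The second question was how KDM1A varies with metabolic and differentiation genes across HCC lines, as the series concerns LSD1 dependence. In the 10 HCC lines that share 1 raw table, KDM1A ranged from 11.04 in Huh-1 to 12.64 in Hep3B. None of 8 relations passed after adjustment, and 1 had an unadjusted p under 0.05. KDM1A was inversely related to the oxidative phosphorylation list, with r = -0.766 (permutation p = 0.011, adjusted p = 0.0883) and rho = -0.709 (permutation p = 0.0259, adjusted p = 0.207), but with median scaling in place of quantiles the direction turned, with r = 0.146 (adjusted p = 0.735). Without the 2 lines farthest from the median of KDM1A, Hep3B and Huh-1, r was -0.299 (permutation p = 0.473), so the relation rests on those lines and on the normalization. Within the larger cluster of 8 lines with low hepatocyte genes, KDM1A and the hepatocyte list had r = -0.0534 (permutation p = 0.896) and rho = -0.119 (permutation p = 0.791), and the hepatocyte and mesenchymal lists had r = -0.511 (permutation p = 0.195) and rho = -0.571 (permutation p = 0.152). Over the 7 lines left without Hep3B, KDM1A and the hepatocyte list had r = -0.603 (permutation p = 0.148) and rho = -0.536 (permutation p = 0.237). The hepatocyte and mesenchymal lists had r = -0.428 there (permutation p = 0.338).

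KDM1A and the mesenchymal list, genes of matrix and motility, had r = 0.539 (permutation p = 0.106, adjusted p = 0.26) and rho = 0.636 (permutation p = 0.0555, adjusted p = 0.222) over the 10 HCC lines. With median scaling the same 10 lines, Hep3B among them, had r = 0.9001 (adjusted p = 0.00152). Without Hep3B and Huh-1, the 2 lines farthest from the KDM1A median, r was 0.967 (permutation p = 0.00017). SNU-739 combined a mesenchymal mean of 10.64 with KDM1A at 12.2, whereas Huh-1 and PLC/PRF/5 combined means of 6.53 and 6.55 with KDM1A at 11.04 and 11.13. Hep3B alone departed, with KDM1A at 12.64 and a mesenchymal mean of 7.55; its array had the lowest signal. Without Hep3B, an alternative chosen after the data were seen, r over 9 lines was 0.972 (permutation p = 7e-05, adjusted p = 0.00056) and rho 0.967 (permutation p = 0.00017, adjusted p = 0.00136). The other relations with KDM1A were r = -0.341 with glycolysis (rho 0.212), -0.52 with hypoxia response (rho -0.212), -0.505 with proliferation (rho -0.0182) and -0.466 with pluripotency and stem cell genes (rho -0.539), with permutation p from 0.13 to 0.329 for r. Without Hep3B r was 0.378 with glycolysis, 0.107 with hypoxia response, 0.493 with proliferation and -0.349 with pluripotency and stem cell genes. With median scaling over the 10 lines it was 0.318, 0.371 and 0.35 with glycolysis, hypoxia response and proliferation. The sign of those relations rests on Hep3B and on the normalization. In the 10 lung and pancreas lines, with each tissue centred on its mean, KDM1A and the mesenchymal list had r = 0.27 (permutation p = 0.485) and rho = 0.345 (permutation p = 0.34), and 0 of 8 relations passed, with the smallest adjusted p at 0.297.

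**Figure D2:**
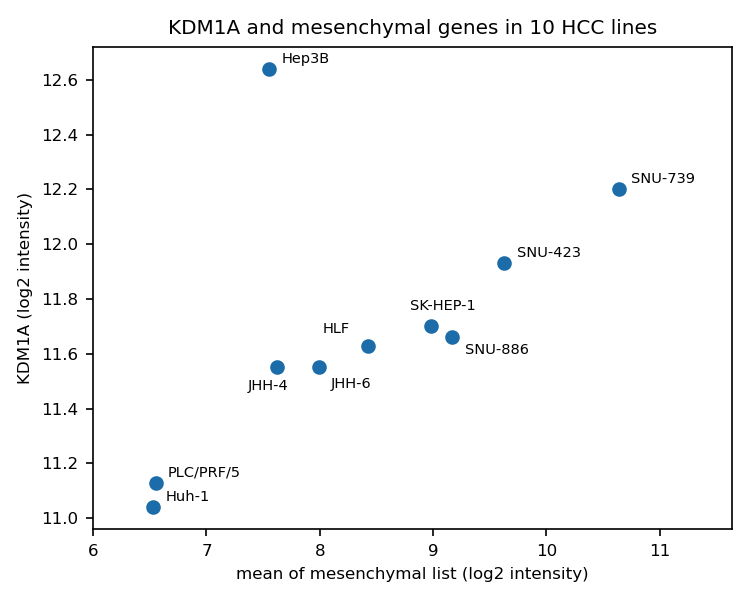
KDM1A (log2 intensity, vertical axis) against the mean of the mesenchymal list (log2 intensity, horizontal axis) in 10 HCC lines that share 1 raw table; each point is a line. Hep3B lies apart at 12.64, and the other 9 lines run from Huh-1 at 11.04 to SNU-739 at 12.2.

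**Figure D3:**
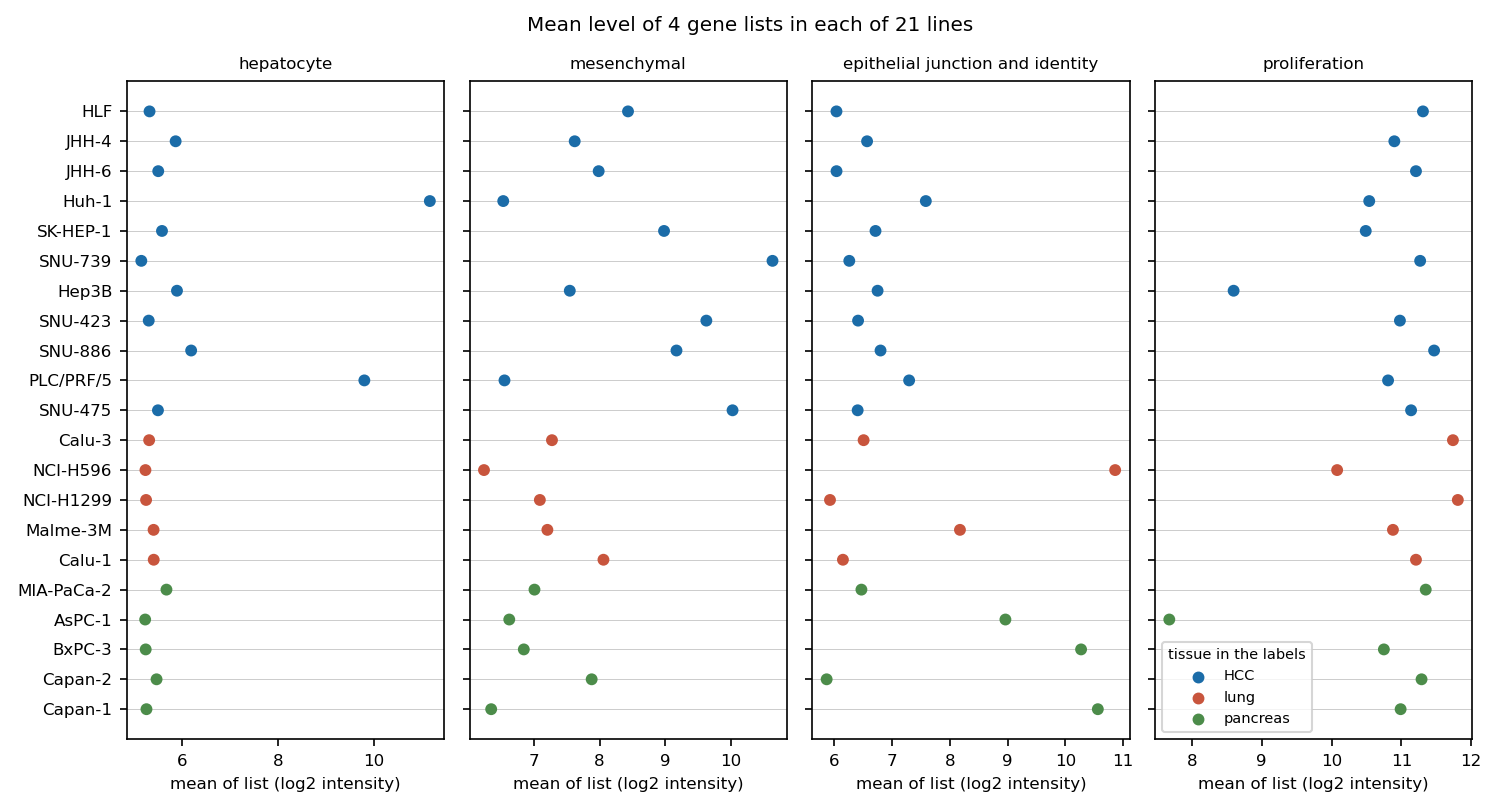
Mean log2 intensity (horizontal axis) of 4 gene lists in each of 21 lines (vertical axis), coloured by the tissue in the labels; each point is a line. Huh-1 and PLC/PRF/5 have hepatocyte means of 11.16 and 9.8, and AsPC-1 has the lowest proliferation mean.

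The third comparison asked what sets HCC lines apart from the lung and pancreas lines, with tissue and array design inseparable. Of 17719 genes tested, 3293 passed (limma), 1162 higher and 2131 lower in HCC lines. CDH2, N-cadherin, averaged 12.72 ± 0.90 in HCC lines (SD, n = 11) against 8.47 ± 3.04 in lung and 8.58 ± 3.36 in pancreas (SD, n = 5 each), 18.4-fold higher with a log2 standard error of 0.92 (adjusted p = 0.00272). SPARC, a matrix glycoprotein, was at least 21.2-fold higher (adjusted p = 0.00218), and it was detected in 9 of 11 HCC lines, 2 lung lines and no pancreatic line. The basement membrane collagen COL4A1 was 17.6-fold higher (adjusted p = 0.00397). SPARC missed the threshold against the lung lines alone (adjusted p = 0.051). KDM1A did not pass, with 11.73 ± 0.45 in HCC, 11.56 ± 0.56 in lung and 11.5 ± 0.33 in pancreas, a log2 difference of 0.20 with a standard error of 0.21 (adjusted p = 0.551).

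Further genes named for their fold were higher in HCC lines. The bone and matrix phosphoprotein SPP1 rose 25.9-fold (limma, adjusted p = 0.0059), the lipid carrier APOE at least 22.6-fold (adjusted p = 0.0151), the carboxypeptidase CPA4 at least 17.3-fold (adjusted p = 0.0147), the mitophagy factor BNIP3 15.9-fold (adjusted p = 0.00665) and the canalicular pump ABCC2 at least 12.99-fold (adjusted p = 0.00118). Against the lung lines alone SPP1, APOE, BNIP3 and CPA4 did not pass (adjusted p = 0.104, 0.113, 0.294 and 0.0547), and BNIP3 had a log2 difference of 2.18 there. CPA4 also missed against the pancreatic lines alone (adjusted p = 0.0763). The serotonin receptor HTR2A and the muscle kinase MUSK were detected in all 11 HCC lines and in none of the other 10, at least 30.8-fold and at least 15.2-fold higher (adjusted p = 1.64e-12 and 9.82e-14).

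The largest falls were POTEF, an actin-like fusion gene, at least 199.6-fold lower (limma, adjusted p = 9.82e-14), the nuclear protein NUCKS1, 35.4-fold lower, ZDHHC4, not detected in any HCC line and at least 28.8-fold lower, FBXL18, detected in 1 HCC line and at least 32.1-fold lower, and the retinal dehydrogenase ALDH1A3, at least 25.7-fold lower (adjusted p = 0.00362, and 0.0798 against lung lines alone). COTL1 was at least 19.97-fold lower, PHRF1 at least 19.5-fold and the ribosomal protein gene RPL7A 18.95-fold. The squamous envelope gene SPRR1A was not detected in any HCC line and at least 13.2-fold lower. Level and detection disagreed for part of these. POTEF averaged 13.53 in the lung and pancreas lines with detection in 4 of 10, and it was detected in 3 of 11 HCC lines. ZDHHC4 averaged 10.1 in the lung and pancreas lines with detection in 6 of 10. The folds of POTEF and ZDHHC4 thus rest in part on signals that missed detection. GPN3 averaged 9.81 with detection in 2 of 10 and in 1 of 11 HCC lines, so no fold is given for it. Every HCC line stood at least 8-fold above every other line in 2 genes and at least 8-fold below in 4, against 1 such gene between lung and pancreas lines within 1 design. These counts are not alike: separating 11 lines from 10 is a stricter demand than separating 5 from 5, and 17719 and 16791 genes were tested.

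**Figure D4:**
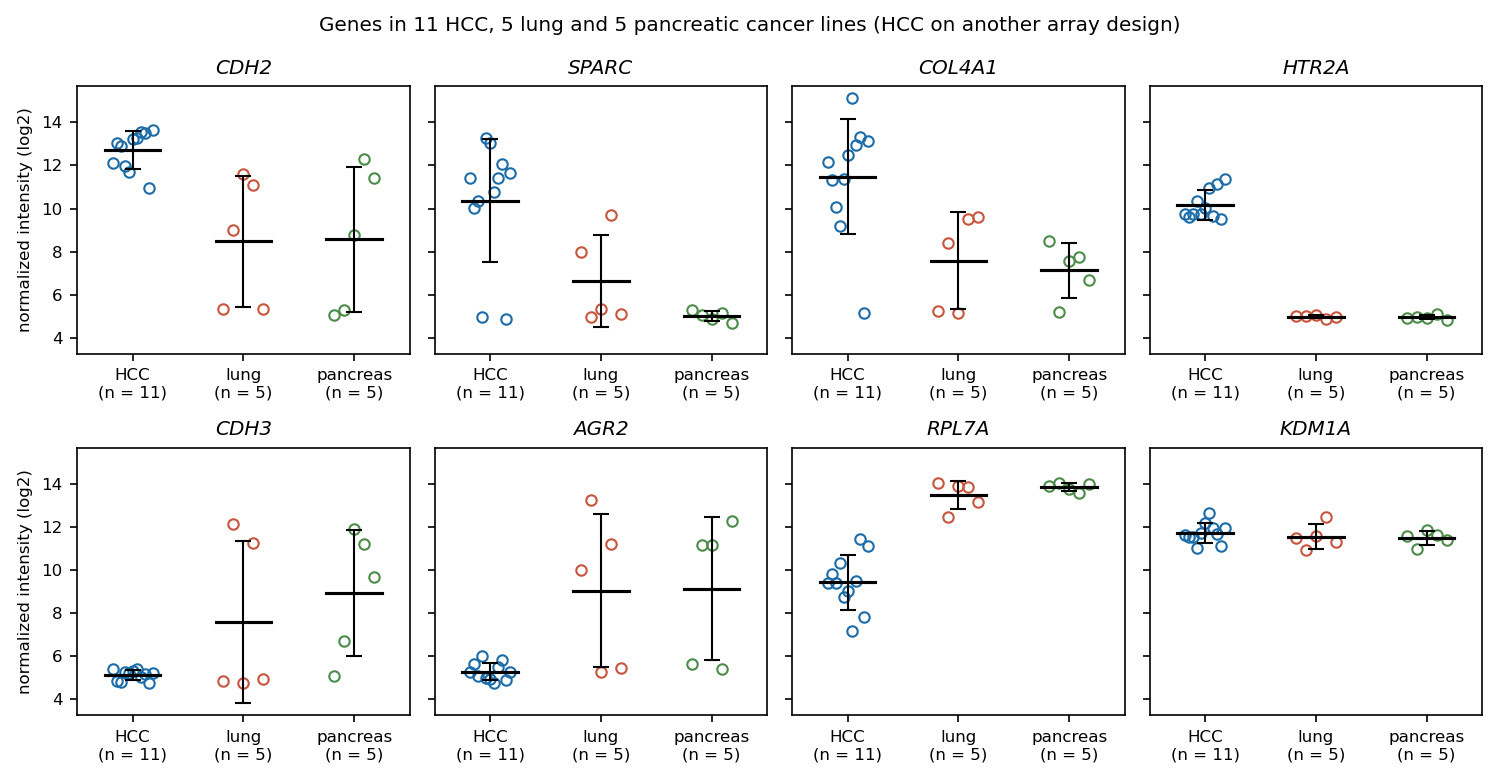
Normalized intensity (log2, vertical axis) of 8 genes in 11 HCC, 5 lung and 5 pancreatic cancer lines; circles are lines, bars are means and error bars 1 SD. HCC lines were read on another array design; CDH2 averages 12.72 in them, and KDM1A 11.73 against 11.56 and 11.5.

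By list, mesenchymal genes were higher in HCC lines, 7 of 32 past the threshold over all genes and 9 adjusted over the list alone, with 30 positive and a median log2 difference of 1.51 (camera, adjusted p = 0.000224, and adjusted p = 0.875 with an estimated correlation). Cancer-testis antigens were positive in 21 of 22 (median 1.65, adjusted p = 0.00192, and adjusted p = 0.875 with an estimated correlation), with 1 past the threshold, SSX4, detected in 4 HCC lines and no other line, and 0 adjusted over the list alone. NRF2 targets, genes of the oxidative stress response, were positive in 21 of 23 (median 0.67, adjusted p = 0.00699, and adjusted p = 0.875 with an estimated correlation); ABCC2 was among 2 that rose, with 1 adjusted over the list alone. Hepatocyte genes were positive in all 19 (median 1.32, adjusted p = 0.00192, and adjusted p = 0.875 with an estimated correlation) and 2 rose, with 1 adjusted over the list alone: the lipid carrier APOM 4.47-fold (adjusted p = 0.0187) and the fibrinogen chain FGA, not detected outside HCC lines and at least 4.86-fold higher (adjusted p = 0.0433). With genes detected in at least 3 lines of each array design, the hepatocyte call was lost (median 0.66, adjusted p = 0.434). APOM missed the threshold against lung alone (adjusted p = 0.0644), against pancreas alone (0.09) and without background correction (0.0502), and SSX4 against lung alone (0.0806) and pancreas alone (0.0763). FGA missed it against lung alone (0.145), against pancreas alone (0.128), without background correction (0.131) and without a filter (0.0538). FGA also lost its call without Huh-1 (adjusted p = 0.0633) and without any 1 of the 10 lung and pancreas lines, at adjusted p from 0.06 to 0.0644. The hepatocyte mean was 11.16 in Huh-1 and 9.8 in PLC/PRF/5 and between 5.16 and 6.19 in the other 8 lines of their raw table. AFP, the fetal albumin, averaged 7.06 ± 2.45 in HCC, was detected in 1 of the other lines and did not pass (log2 difference at least 1.67, adjusted p = 0.116). With the raw table as a random block AFP passed (limma, adjusted p = 0.0464), though each table holds 1 side.

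Epithelial junction and identity genes were lower in HCC lines, with 7 of 29 past the threshold, 8 adjusted over the list alone, 25 negative and a median of -1.44 (camera, adjusted p = 0.00321, and adjusted p = 0.875 with an estimated correlation). P-cadherin, CDH3, was not detected in any HCC line and at least 7.96-fold lower (limma, adjusted p = 0.022), and the protease PRSS8 was at least 5.78-fold lower (adjusted p = 0.0127). Against lung lines alone neither passed (adjusted p = 0.195 and 0.17). The list mean in Calu-3, NCI-H1299, Calu-1, MIA-PaCa-2 and Capan-2 was 5.87 to 6.51, in or below the HCC range of 6.04 to 7.58, so the difference came from NCI-H596, Malme-3M, AsPC-1, BxPC-3 and Capan-1, with 8.17 to 10.86. With genes detected in at least 3 lines of each array design the epithelial call was lost (median -1.11, adjusted p = 0.189). Ribosomal protein genes were negative in 31 of 40, with 10 past the threshold, 11 adjusted over the list alone and a median of -0.34 (camera, adjusted p = 0.00566, and adjusted p = 0.875 with an estimated correlation); RPL13A fell 4.08-fold and RPL13 3.18-fold, RPL13 missing the threshold against lung alone (adjusted p = 0.0603). Their log2 differences had an SD of 0.51, against 0.156 between lung and pancreas lines within 1 design. With median scaling, which moved the median of all genes from -0.02 to -0.20, the epithelial and ribosomal lists had medians of -1.38 and -0.38 and lost their calls (adjusted p = 0.071 and 0.33), the ribosomal list lying nearer to all genes than before.

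Lists without a call held single genes that passed. The luminal secretory gene AGR2 was at least 12.5-fold lower (limma, adjusted p = 0.00729), the squamous serpin SERPINB5 at least 9.91-fold lower (adjusted p = 0.0125, and 0.102 against lung alone) and the ubiquitin-like modifier ISG15 4.83-fold lower (adjusted p = 0.000974). Among hypoxia genes P4HA2 was 2.59-fold higher and HILPDA 3.79-fold lower. Among respiratory chain subunits NDUFB8 was 1.80-fold higher (adjusted p = 0.0103, and 0.108 against pancreas alone) and NDUFA10 3.20-fold lower. The cell cycle regulator E2F1 was detected in 0 of 11 HCC lines and 10 of 10 others, at least 3.52-fold lower (limma, adjusted p = 6.75e-08). The proliferation list had a median of 0.14 without a call (camera, adjusted p = 0.7875), and tissue and array design cannot be told apart for E2F1. The citrate lyase ACLY was 2.60-fold higher (limma, adjusted p = 0.00299). Of 19 members of the LSD1-CoREST complex list 2 rose and 2 fell, the same numbers adjusted over the list alone, with the remodeller CHD4 2.09-fold higher (adjusted p = 0.00938) and the repressor GFI1 at least 2.65-fold lower (adjusted p = 0.00349). KDM1B, the second flavin-dependent demethylase and the other one counted as a fall (adjusted p = 0.0156), was detected in 1 of 11 HCC lines and 3 of 10 others, with means of 5.06 and 5.61 near background, so no fold is given. CHD4, GFI1 and KDM1B did not pass against lung lines alone (adjusted p = 0.0975, 0.241 and 0.104).

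With an estimated inter-gene correlation 0 of the 31 lists passed. By fry the mesenchymal, ribosomal, lung epithelium and melanocyte lists passed (adjusted p = 0.0371). Against lung lines alone 1756 genes passed and against pancreatic lines alone 2076. With genes detected in at least 3 lines of each array design, chosen after the data were seen, 1434 genes passed, and with the raw table as a random block 5352.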

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

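The tests of a failed array, a swap, low signal on the array and the array designs, the deletion test on CDKN2A and MTAP and the fits without named libraries were chosen after their results were seen; the splits and the tests on prostate, kidney, undetected neighbours and raw signals were written before they were run. Chance puts about 1 in 20 groups past the criterion used here; of 128 groups of 5 values examined, 19 had a sample far from the other 4.

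In the lung group, the chromatin regulators list averaged 8.66 in the library labelled Malme-3M against 8.51 to 8.53 in the others. Percent detected was 40.7 in Calu-3 against 43.5 to 43.6. CDX2 stood at 6.45 in Calu-1, MUC13 at 9.46 in Malme-3M and CD14 at 7.71 in Calu-3, each above the other 4 lung lines. COL6A2 at 5.58, LDHB at 12.75 and CENPF at 9.33 were low in NCI-H596. In the pancreatic group, the squamous and basal list averaged 10.97 in BxPC-3 against at most 6.74 elsewhere, and the neuroendocrine list 7.45 in Capan-2 against at most 5.86. The acinar and islet list averaged 5.38 in MIA-PaCa-2, below the other 4. In AsPC-1 the proliferation list averaged 8.04 and TPX2 was 8.45, both low. In BxPC-3, CDX2 at 7.09 and PLCG2 at 8.75 were low and CSAG2 at 8.22 and CSAG1 at 9.81 were high. SFR1 was high in MIA-PaCa-2 at 10.77, and BNIP3 in Capan-2 at 11.97.

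The library labelled Malme-3M, a melanoma line, held little of a melanocyte program: TYR read 4.94 and MLANA 5.02, PMEL 7.39, the highest of the 10 libraries but next to 7.22 in AsPC-1, and the list mean of 5.83 was the highest in the lung group but under 5.92 in Capan-2, while FOXA1 read 13.56, SPDEF 10.92, HOXB13 12.36 and the secreted protein gene MSMP 15.56. A failed array is argued against by 43.64% of genes detected, and a swap within the 10 lung and pancreas libraries by the lack of a partner, as the highest melanocyte mean of the other 9 lay 0.392 above their median. A candidate explanation is a prostate line under this label; 5 of the 15 prostate epithelium genes detected in any library were highest here (HOXB13 and MSMP were left out of that list), with KLK2 undetected in all 10, which leaves it open. Genes that missed the detection call in this library alone, with CTNNA1 at 5.14 but also the bright PRXL2A at 11.31, included a run of 5 neighbouring measured genes, KAT2A, RAB5C, GHDC, STAT3 and CAVIN1: 27.8% of 18 such genes had another within 5 measured genes, against a 95th percentile of 11.1% in random sets (permutation p = 0.0019), consistent with loss of neighbouring genes. PC-3, a prostate line known to lack CTNNA1 and STAT3 and the source in which MSMP was named, would meet these values, and genotyping was not available here. The neighbour test was run in 10 libraries and its p is not adjusted for them. The share also exceeded the random 95th percentile in BxPC-3 (28.6% against 14.3%) and Capan-2 (19% against 14.4%), so it is not particular to this library.

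The library labelled Hep3B stood apart from the other HCC lines. Low signal fits part of it, with a 95th percentile at 4.781 times background against at least 10.1 in the other 9 lines of its table, and a median of 0.341 times their signal over 40 ribosomal protein genes. As the whole cause it is argued against by 88 genes with raw signal over background at least 4 times that of any other line of the table, where the median of the other 9 lines was 40; among them NAPSA read 5309 against at most 25, CDH16 2358 against 56 and HAVCR1 3250 against 191. A kidney line under this label may explain these, since NAPSA, CDH16 and HAVCR1 are known from renal epithelium. NAPSA is also a member of the fixed lung epithelium list, and these genes were picked from those highest in this library. Of 18 kidney epithelium genes detected in any HCC library, 5 were highest here (PAX8 10.62, CDH6 11.85, GGT1 11.29, PDZK1 11.27, SLC22A6 8.73), too few to decide by the bound set beforehand. AFP, which the named line is known to make, read near background at 4.93.

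The 3293 calls between HCC lines and the others exceeded those of every other split: 1 of 100 splits, the real one, gave as many, and the highest other gave 2. Every HCC array is of another design and the other splits mix the designs, so a difference of design alone could give this. The splits exclude chance for a difference between the 2 sets of arrays, but they do not test it for tissue. Of 40 ribosomal protein genes, 4 passed with over 2-fold, where the bound for an effect of design was 5. Outside the fixed list, and looked up after the count was seen, RPL7A (18.95-fold) and RPL31 (3.44-fold) fell and RPL10L rose 4.70-fold, which would carry the count past that bound, so that an effect of design is not excluded and tissue and design cannot be told apart for single genes. With the raw table as a random block 5352 genes passed, at a correlation within tables of -0.0354, which decides nothing since each table holds 1 side. The 6 lists called in this comparison were matched or exceeded in 71 of 100 splits, with 15 the highest, so chance is not excluded for the number of lists.

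Between lung and pancreas lines chance cannot be excluded for the number of genes or of lists: 23 of 100 splits gave at least 1 gene, and 51 of 100 gave at least 6 lists, with 15 the highest. This count of genes takes no account of how strongly BTBD6 itself differed (limma, adjusted p = 4.23e-06). The highest other split called 102 genes, which points to another structure of the samples. It set Calu-3, NCI-H1299, Calu-1, MIA-PaCa-2 and Capan-2, with epithelial means from 6.21 to 6.91 over the genes tested, against NCI-H596, Malme-3M, AsPC-1, BxPC-3 and Capan-1, with 8.85 to 11.82. E-cadherin, CDH1, was lower in the first 5 by at least 6.87 on the log2 scale, the claudin CLDN7 by at least 6.63, the receptor MST1R by at least 4.78 and the anchoring filament protein LAD1 by at least 5.85. This split was picked as the largest of those drawn, so its count is not a test.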

How the results depend on the processing

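The fits without named libraries, with the background fitted by limma, with genes detected in both designs and the KDM1A relations without Hep3B were chosen after the data were seen; the other alternatives were planned. BTBD6 passed in every fit of the lung and pancreas lines alone, at 4.40 without background correction and with the deposited values, and missed in the fit of all 21 lines. With the background fitted by limma its difference was 0.00214, since that fit compresses all values, and no agreement or loss under it counts as a test. The count of 1 gene between lung and pancreas lines became 2 with detection p under 0.01 in at least 5 lines, 2 with array weights, 3 without Calu-3, Malme-3M and Capan-2, and 1 to 4 with 1 line left out; the cause was not tested. The 3293 calls between HCC lines and the others became 1662 with the stricter detection filter and 1434 with genes detected in at least 3 lines of each design, both of which test fewer genes, and 1776 with a 2-fold minimum, a subset by construction. They became 1756 against lung alone and 2076 against pancreas alone, which use fewer samples. They became 4495 with no filter, which tests more genes, 4217 with median scaling, 2858 of them shared and 29% higher in HCC lines against 35.3%, 4189 with array weights, 5352 with the raw table as a random block, 2184 with the compressed background fitted by limma, and 2832 to 3796 with 1 line left out; for these the cause was not tested.

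The 6 lists of the lung and pancreas comparison became 0 with an estimated correlation, 0 with fry and 0 to 10 with 1 line left out. The 6 lists of the HCC comparison became 0 with an estimated correlation and stayed at 6 to 7 with 1 line left out. The similarity difference ranged from -0.00944 to 0.00575 with 1 line left out, with its sign turned without MIA-PaCa-2 (0.000793) and Capan-2 (0.00575). No relation of KDM1A across HCC lines passed as reported, against 1 with median scaling (smallest adjusted p = 0.00152), 1 without the 2 farthest lines and 1 without Hep3B; each time this was the mesenchymal list. The oxidative phosphorylation relation turned to r = 0.146 with median scaling. Across HCC lines the relations with glycolysis (r = 0.318), hypoxia response (0.371) and proliferation (0.35) also turned from negative to positive there. In the lung and pancreas lines the relation with pluripotency and stem cell genes turned to 0.0363.

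The KDM1A difference turned to -0.0688 in the HCC comparison with median scaling, and in the lung and pancreas comparison to -0.166 without Malme-3M, -0.0613 without AsPC-1 and -0.182 without Calu-3, Malme-3M and Capan-2, with -0.166 to 0.202 over single lines left out. The LSD1-CoREST list, never called, changed the direction of its test without a filter (median 0.0726) and without NCI-H1299 (0.000775), Malme-3M (0.0268), AsPC-1 (-0.0017) or Capan-1 (-0.0582), with medians from -0.0582 to 0.189. The causes were not tested. Of 41 genes named in the HCC comparison, 16 lost their call against lung alone, 5 against pancreas alone and 2 without background correction. Over all 140 genes the naming rule picked there, 4225 of 4648 values kept direction and side of the threshold and 48 genes lost a call in at least 1 fit; of the 41 named, 17 did. In the lung and pancreas comparison 2491 of 2543 values over 131 genes were kept, almost all of them without a call. The fit by limma is not in these counts. Planned but not run were the slide as a block, since no slides are given, and, in the HCC comparison, the deposited processed values and SNU-475 alone, since HCC and the others lie in different processed tables. Signal over background was lowest in Hep3B, with a 95th percentile of 4.781 times background.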

Other observations

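The correlation without Hep3B and the test on CDKN2A and MTAP were chosen after the values were seen; the rankings of KDM1A among all genes were written before they were run but after that correlation was seen.

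Single libraries held gene programs that no comparison describes. The library labelled Calu-3 had chromogranins and secretogranin, markers of neuroendocrine granules, at 12.55 for CHGA, 13.12 for CHGB and 14.71 for SCG2, with CDH1 at 4.90. The library labelled Capan-2 had the simple-epithelium keratins KRT8 at 5.55 and KRT18 at 6.79, where the other 9 lung and pancreas libraries had at least 11.05 and 14.27, and vimentin, VIM, at 15.45. The libraries labelled Calu-3 and Capan-2 are among those whose markers depart from their labels, and their identity was not checked here. BxPC-3 carried the basal genes KRT5 at 13.24 and TP63 at 12.01. The interferon response list averaged 11.40 in Calu-1 and 10.37 in NCI-H596 against 6.89 in Calu-3. RB1, the retinoblastoma gene, read 6.22 in NCI-H596 and at least 8.85 in the other 9. NRF2 targets averaged 12.64 in Huh-1 and 8.75 in SNU-739.

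Tumour suppressor transcripts were missing in single lines. CDKN2A read 5.07 in Calu-1, 5.14 in MIA-PaCa-2, 5.23 in BxPC-3 and 5.12 in Capan-1 and at least 9.09 in the other 6 lines, and MTAP, known as its chromosomal neighbour, read 5.2, 6.18, 5.65 and 5.27 in the same 4 lines and at least 9.88 in the others. MTAP was still detected in MIA-PaCa-2, where CDKN2A was not; in the other 3 lines neither was. The pair was picked because both read low in the same lines, so their correlation of 0.963 restates these values and does not test a joint loss, and copy number was not measured. In BxPC-3, SMAD4 read 4.95 and the neighbouring measured genes ME2 and MEX3C 5.07 and 4.93, and the neighbours PSAP and ASCC1 5.42 and 5.04 against at least 13.22 and 10.72 elsewhere; 28.6% of its 14 genes undetected there alone had another nearby (permutation p = 0.01, not adjusted for 10 lines).

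A hypothesis on KDM1A is that its level follows the mesenchymal transcripts among HCC lines. Over the 9 lines without the library labelled Hep3B, 0 of 17686 other genes outside the list had a higher correlation with the list mean than KDM1A at 0.972, so that 100% lay below it, and 12 genes exceeded 0.9. SNU-475, in another raw table and not among the 9, left r at 0.975 over 10 lines when added. The set of 9 lines was chosen because KDM1A departed in Hep3B. With the left-out line chosen for each gene as the one that raised its own correlation most, 100% of the genes again lay below KDM1A, but with no line left out 1004 genes exceeded its 0.539 over the 10 lines, and the relation was picked out of 8. KDM1A had r = 0.373 with the signal over background of the arrays. KDM1A spans only 11.04 to 12.2 in these lines, and the lung and pancreas lines had r = 0.27, so the relation may be limited to HCC lines or to this array set, and the difference between the sets was not tested.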
